A study of Mus musculus with 10 samples.

How the data were processed

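The series holds 10 CEL-seq2 libraries from crypts of the mouse small intestine. CEL-seq2 primes on the poly(A) tail, amplifies by in vitro transcription and tags each molecule with a random barcode. Per the labels, 7 libraries hold sorted single cells and 3 hold mouth-pipetted doublets or triplets, each in a plate of 384 wells with ERCC spike-in RNA. Groups were taken from the sample titles, and replicates were numbered within each group. The titles also carry experiment codes: GK5a for sorted replicates 1 to 5, GK5b for sorted replicates 6 and 7, and JC for picked replicates 1 to 3. In full, the GK5b codes end in G and L, and the picked codes are JC68, JC71 and JC72. The titles do not explain these endings, so libraries of the same code may differ in ways not given. The code is confounded with the group, so it could not enter a model. Means within GK5a and within GK5b are given for values per well, for wells with several classes, and for named genes that passed and in which they differ more than 2-fold. The labels do not say which libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

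Per the submitters' processing notes, reads were aligned with BWA 0.6.2-r126 to mm10. The counting software, its strand setting and any filter on wells are not given in the sources used here. The deposited values are molecule count estimates per gene and well, not normalized across wells: the deposited tables hold numbers that are not whole but map back to whole barcode counts under the authors' correction for molecules that share a barcode. In every library 100% of the values were whole after that step, within 0.001. The tables are tab-separated under another extension and their unit was recorded as other, for which no count model was run. Tables list between 12292 and 14835 genes per library, 18022 over all libraries, and 85 spike-in species. No mitochondrial gene is listed, so the mitochondrial list could not be tested. Gene names are those of the tables, and positions come from the GENCODE annotation of the GRCm38 assembly, which is mm10.

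Wells with at least 1000 transcripts of endogenous genes were used: 1615 sorted and 501 picked. Spike-ins were left out of totals and tests. All 24 pairs of libraries within a group differed by more than sampling noise, with a chi-square per gene from 4.37 to 40.1, so none looked like 1 library deposited again, and each was counted once. This does not show that they are independent. The values were 4.37 to 8.23 between GK5a libraries, whose titles share the code GK5a-M2, and 17.6 to 40.1 between GK5a and GK5b. No doublet caller was run, because the picked wells were meant to hold several cells. The sorted wells, treated in the same way, give the background. Shares of wells have counting error on 122 to 264 wells per library.

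For genes, the deposited values of the used wells were summed per library, scaled by trimmed mean of M values (TMM, factors from 0.756 to 1.11) and tested as log2(CPM + 1) with limma 3.58.1 (lmFit and eBayes with trend) in R 4.3.3. A gene entered with at least 10 transcripts at the median library size in 3 libraries and 15 in total, which left 10427 genes. Benjamini-Hochberg adjusted p under 0.05 made a call. The design fixed in advance named a negative binomial quasi-likelihood test and a Wald test as its alternative. Neither was run. The whole barcode counts would have allowed both. The layout of the columns kept the unit from being checked by the tool used for it, so it was entered as other, and limma took their place after that. On sums of the whole barcode counts limma called 3154 genes. Fold changes are on the log2(CPM + 1) scale and understate the change of low genes. On data simulated from the sorted libraries over 10185 genes, this test recovered 66% of 100 genes changed 2-fold and 96% of 100 changed 4-fold, and called 13 of 9985 unchanged genes. Both simulated groups had the spread of the sorted libraries and no difference in experiment code or sex. These numbers therefore do not measure recovery or false calls between the real groups.

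Gene lists were fixed in advance: 10 of cell markers (stem, Paneth, goblet, enteroendocrine, enterochromaffin, tuft, enterocyte, immune, stromal or endothelial, erythroid) and 11 of processes (proliferation, immediate-early, heat shock, unfolded protein, p53 targets, junction and adhesion, niche ligands, Notch targets, RNA quality, mitochondrial, ribosomal protein). Of these 21, 18 had at least 3 tested members. They were tested with camera from limma on the same values, with a preset inter-gene correlation of 0.01, two-sided, adjusted over the 18 lists. With 1 list shifted by 0.5 on the log2 scale in simulated data, camera called it and 0 of the 17 others. Genes were drawn independently in these data, so they hold no correlation between genes. The 0 therefore does not measure false list calls in the real libraries.

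The rule for named genes was fixed in advance too. It takes, among called genes with an average of at least 20 CPM whose 3 picked libraries all lie above or all below the 7 sorted ones, the 12 largest rises and the 12 largest falls. It adds up to 4 members per list with the lowest adjusted p, and Lgr5, Olfm4, Lyz1, Muc2, Chga, Tac1, Dclk1, Mki67 and Apoa1 always. The rule picks 97 genes. Only the 71 that passed the threshold or are always named are given as results of the gene test and in the checks of other settings. This restriction was made after the data and the other settings had been seen. CPM values of named genes are TMM-scaled.

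Single values per library were compared with two-sided exact permutation tests (scipy 1.17.1). With 7 against 3 libraries there are 120 splits, and the smallest possible p is 0.0167. Against the 2 GK5b libraries alone it is 0.2, which cannot pass 0.05. Log2 odds ratios of 2 marker genes in 1 well had 0.5 added to each of the 4 counts of wells. Genes per well were counted after thinning each well to 2000 transcripts, which left out 181 sorted and 118 picked wells.

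For cell classes, the sorted wells were clustered on log-normalised whole barcode counts (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0, leidenalg 0.10.2). The 16 clusters were named from markers fixed in advance. A name needed at least 3 raised markers (log2 fold over 1), at least 1 marker among the 10 leading genes and no other class with more there; leading genes needed 50 CPM and detection in 20% of the wells. This scoring, and the merging of stem and dividing clusters into 1 progenitor class, were settled after the clusters had been seen. Of the clusters, 1 stayed unnamed. Every well was then fitted by non-negative least squares as a mixture of the cluster profiles over 1999 genes, with Rn45s left out after the data had been seen. A class counted as present at a weight of at least 0.25. The profiles come from the sorted wells themselves, so names and weights describe the picked wells by the sorted ones. Pairs of classes were set against 1000 shuffles within each picked library that keep the number of wells per class and of classes per well.

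Tests, lists, markers, depths and a first set of other settings were chosen before the data were examined. That set covered scaling, filters, the well minimum, the weighting of wells, the sorted libraries used, the weight threshold, cluster resolution, depth and leaving out each library in turn. Others were added after seeing the data: other pseudocounts, precision weights, whole barcode counts, removal of Rn45s, of the first 72 wells of picked replicate 1 or of the 5 Paneth-richest wells of each library, progenitor wells alone, reference profiles from other libraries, and genes per well without abundant gene groups. Marrow, epithelial, kidney, stomach and sex-linked lists were also written after the data had been seen. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9.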

Results

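Transcripts were counted in single cells sorted from dissociated mouse small-intestinal crypts (7 libraries) and in small groups of cells, doublets or triplets, picked by mouth after a milder dissociation (3 libraries). Crypts hold the dividing stem and progenitor cells of the gut lining together with Paneth cells, which secrete antimicrobial peptides. The comparison asks which transcripts and which cell classes the picked groups hold beside those of single cells. The used wells of the sorted libraries held from 1022859 to 4832581 transcripts per library, and those of the picked libraries from 821829 to 1232614. The sorted libraries had from 189 to 264 used wells and the picked libraries had 122, 179 and 200.

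The picked and sorted libraries came from mice of different sex. Xist, the RNA that silences an X chromosome in females, was at 132 ± 20.3 CPM of library totals (SD, n = 3) in picked and 0.27 ± 0.38 (n = 7) in sorted libraries. The Y-linked gene Ddx3y was at 77.3 ± 16.2 CPM (SD, n = 7) in sorted libraries and had 0 transcripts in the picked ones, at least 82.9-fold lower against a floor of 3 counts over the group. Eif2s3y was at 73.7 ± 13.8 CPM in sorted libraries, likewise with 0 in picked libraries, at least 79.0-fold lower. Every gene difference below is therefore also a difference between animals, sexes and experiment codes. Whether the strain differs between some libraries is open too, as given for Pla2g2a below. Neither a picked male nor a sorted female library was analysed here.

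Of 10427 genes tested, 3136 differed between picked and sorted libraries (limma, adjusted p under 0.05): 1503 were higher and 1633 lower in picked libraries. Among the called genes, 1289 had all 3 picked libraries above all 7 sorted ones and 1164 had all 3 below. In all, 25.8% of tested genes were separated in this way. Chance gives 1.67% if the libraries are interchangeable, which they are not, since those of the same experiment code are more alike within GK5a. The largest rises, besides Xist and members of the Paneth list, were in Rpph1, the RNA of ribonuclease P (96.0 ± 44.4 against 0.22 ± 0.28 CPM, adjusted p = 7.95e-07), 2310014L17Rik (487 ± 72.3 against 1.89 ± 2.15, adjusted p = 2.21e-06), Scand1, Kif3a, Leprel2, H2-Q4 and Ctla2a. Kif3a, a kinesin motor subunit, was at 866 ± 617 CPM (SD, n = 3) against 21.3 ± 11.8 (n = 7). The largest falls, besides the Y-linked genes, were in Arpc3, a subunit of the complex that nucleates branched actin, and in Prcp, Prmt1, Crebbp, Glg1, Cnot6, Hook1, Mt2, Cstf2t and the goblet gene Rep15. Arpc3 was at 38.2 ± 7.68 CPM in picked and 185 ± 9.40 in sorted libraries (log2 fold change -2.27 ± 0.14 SE, adjusted p = 7.95e-07), with means of 185.4 in GK5a and 185.5 in GK5b.

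The number of genes called was 3231 against GK5a libraries alone, 1452 against GK5b libraries alone and 1457 with the 5 GK5a libraries summed into 1. The balance of higher and lower calls moved with the scaling, the libraries and the weights. With library totals in place of TMM, 859 genes were higher and 3422 lower, the share of higher calls went from 47.9% to 20.1%, and the median log2 fold change of all genes from -0.07 to -0.39. The mean of CPM per well, which gives every well the same weight, gave 1022 higher and 3162 lower. The balance went the other way with GK5a summed (941 higher, 516 lower), against GK5b alone (884 and 568) and with precision weights in limma (1338 and 799).

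Among the genes with a difference, some also varied between the experiment codes of the sorted libraries. Mt2 averaged 258 CPM in GK5a and 82.7 in GK5b, Rep15 55.0 and 262, Reg4 82.3 and 191.5, Apob 93.4 and 38.6, Ghrl 9.77 and 49.1, Kif3a 15.9 and 34.6, Leprel2 6.76 and 17.3, and 2310014L17Rik 0.680 and 4.91. Hspa1a was at 12.1 and 4.37 CPM, Hspa1b at 38.1 and 13.5, Defa5 at 7.79 and 22.9, Defa3 at 6.85 and 3.15, Gm15315 at 2.17 and 5.00, Scand1 at 4.61 and 2.18 and Areg at 3.79 and 0.936.

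Ribosomal protein genes rose together in the picked libraries. Of 76 tested members 59 were higher and 0 lower over all genes, and 65 were higher adjusted over the list alone. The median log2 fold change was 0.99 (camera, adjusted p = 1.17e-26, and adjusted p = 0.0195 with an estimated correlation). With each library's trend on transcript length and GC content removed, it went from 1.00 to 0.54 over 75 members with a value, and the members called higher from 59 to 44 (camera, adjusted p = 2.9e-15). Rpl38 was at 3408 ± 132 CPM (SD, n = 3) against 806 ± 91.1 (n = 7), a log2 fold change of 2.09 ± 0.13 (SE). Rpl36 was at 3388 ± 221 against 614 ± 148, Rpl35 at 3390 ± 249 against 1120 ± 67.3 and Rps19 at 3875 ± 269 against 1295 ± 144. Together these genes took 18.2 ± 1.81% of transcripts in picked and 12.8 ± 0.725% in sorted libraries (exact permutation p = 0.0167). Ribosomal protein genes have many near-identical pseudogenes, so the level of a single member is uncertain. In the same libraries the ribosomal RNA precursor Rn45s was 6.61-fold higher. It also differed between the sorted codes, with 2610 to 4087 CPM of library totals in GK5a and 8988 and 9259 in GK5b libraries. The nuclear RNA Malat1 was lower (log2 fold change -1.47, adjusted p = 0.0041, limma), though picked replicate 1 (933 CPM) lay above sorted replicate 5 (901.5). The other 2 of the 3 tested RNA quality genes were not called.

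Immediate-early genes, which cells switch on within minutes of a stimulus or of handling, were also higher. Of 20 members 14 were higher and 0 lower, and the same numbers held adjusted over the list alone. The median log2 fold change was 1.52 (camera, adjusted p = 2.93e-09), and the list had an adjusted p = 0.0722 with an estimated correlation. Ier3 was at 84.8 ± 26.3 CPM against 10.6 ± 1.89, Junb at 271 ± 60.6 against 48.3 ± 10.1, Dusp1 at 102 ± 34.1 against 16.0 ± 2.12 and Fosb at 188 ± 37.0 against 24.5 ± 8.30 (limma, adjusted p between 4.39e-06 and 1.17e-05). Within the sorted group Fosb averaged 27.5 CPM in GK5a and 16.9 in GK5b. The shifts of Rn45s and Malat1 go with this group too.

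Heat-shock genes, chaperones that refold proteins, followed with 8 of 11 members higher and 0 lower, and 9 higher adjusted over the list alone. Their median log2 fold change was 0.70 (camera, adjusted p = 4.51e-05, and adjusted p = 0.0252 with an estimated correlation). Hspa8 was at 3241 ± 382 CPM against 1572 ± 166 and Hsph1 at 149 ± 29.4 against 56.9 ± 8.09, beside the same shifts of Rn45s and Malat1. The stress-induced Hspa1a was at 121 ± 63.8 against 9.87 ± 6.66 and Hspa1b at 236 ± 96.5 against 31.1 ± 17.3; these 2 genes are nearly identical, so reads cannot be shared out between them with certainty.

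**Figure D1:**
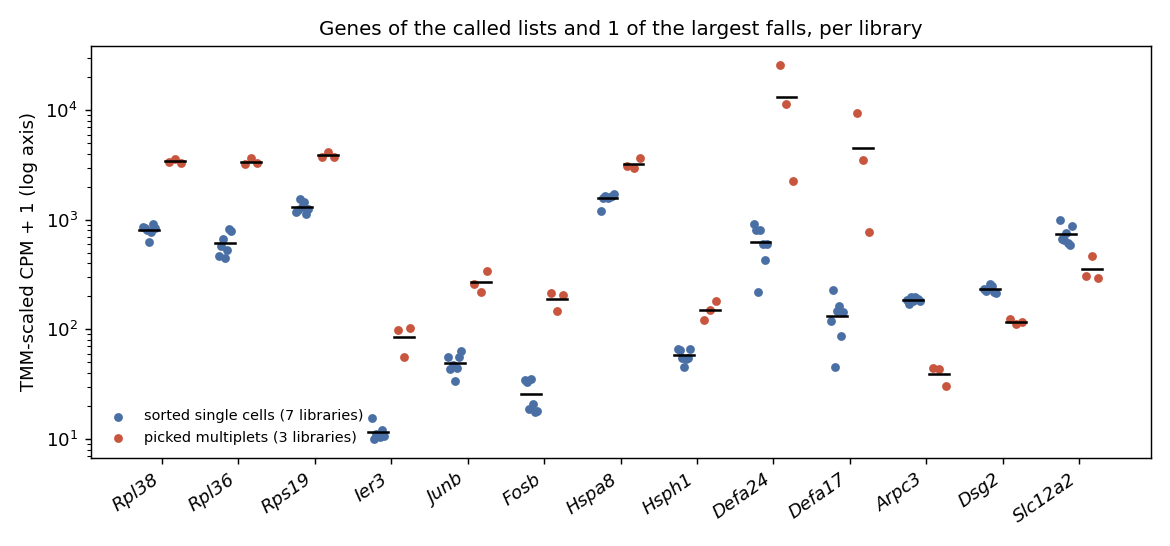
TMM-scaled CPM plus 1 on a log axis for 13 named genes, with 1 point per library (blue, 7 sorted; red, 3 picked) and a bar at each mean. The 3 picked libraries lie above all 7 sorted ones for the first 10 genes, from Rpl38 to Defa17, and below them for Arpc3, Dsg2 and Slc12a2.

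Transcripts of Paneth cells were higher in picked libraries, with wide variation between them. Of 25 members of the list 15 were higher and 0 lower, and 17 were higher adjusted over the list alone. The median log2 fold change was 2.92 (camera, adjusted p = 4.64e-07), but the list had an adjusted p = 0.773 with an estimated correlation. With each library's trend on transcript length and GC content removed, the median went to 1.97 over 21 members with a value. Of these, 8 were then called higher in place of 13 (camera, adjusted p = 8.18e-05). The defensin gene Defa24 was at 13260 ± 12010 CPM (SD, n = 3) against 624 ± 244 (n = 7), Defa17 at 4551 ± 4373 against 132 ± 58.6, Defa3 at 301 ± 261 against 5.80 ± 4.48, Defa5 at 480 ± 675 against 12.1 ± 9.65 and Gm15315 at 67.7 ± 50.3 against 2.98 ± 2.86. Defensin genes are close paralogs and their single levels are uncertain. Lyz1, the lysozyme of Paneth granules, was at 13000 ± 14420 against 2347 ± 1415 CPM (adjusted p = 0.108, limma). Its log2 fold change of 1.70 went to 0.16 with the mean of CPM per well (adjusted p = 0.839, limma), to 0.625 without picked replicate 1 and to 2.96 without picked replicate 3, where it was called (adjusted p = 0.00371, limma), as it was in progenitor wells (2.60, 0.00457). The list took 13.6%, 4.95% and 1.19% of the transcripts of picked replicates 1, 2 and 3, against 0.999 ± 0.493% in sorted libraries (SD, n = 7; exact permutation p = 0.05).

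Stem cell genes fell in picked libraries: 7 of 16 members were lower and 0 higher, and 8 were lower adjusted over the list alone. Their median log2 fold change was -0.69 (camera, adjusted p = 0.0306), with an adjusted p = 0.905 with an estimated correlation. The call was lost with fry in place of camera (adjusted p = 0.122), with library totals in place of TMM (median -1.01, adjusted p = 0.146), against GK5b libraries alone (-0.35, 0.397), and without sorted replicate 7 (-0.68, 0.0541), picked replicate 1 (-0.52, 0.105) or picked replicate 3 (-0.66, 0.106). Slc12a2 was at 356 ± 94.1 CPM against 735 ± 151, Rgmb at 16.5 ± 4.64 against 51.1 ± 23.9, Nrn1 at 6.73 ± 5.70 against 15.6 ± 2.97 and Gkn3 at 6.85 ± 3.56 against 18.8 ± 7.26; the last 3 kept their calls in 23, 22 and 22 of 27 settings. Lgr5, the marker of crypt base stem cells, was at 38.5 ± 5.54 CPM against 74.5 ± 31.2 (adjusted p = 0.32, limma), with means of 88.6 in GK5a and 39.1 in GK5b. Against GK5a libraries alone, both the stem list (adjusted p = 0.00115, camera) and Lgr5 (log2 fold change -1.13, adjusted p = 5.74e-04, limma) were called lower. Leaving out sorted replicate 6 was enough for Lgr5 to be called (-1.09, adjusted p = 9.33e-04, limma), and Lgr5 was also lower in progenitor wells (-1.78, 0.00593). Olfm4, another stem cell gene, was at 6.84 ± 2.47 against 6.14 ± 3.07 CPM (adjusted p = 0.735).

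Genes of cell junctions and adhesion went both ways. Of 27 members 4 were higher and 12 lower, the same numbers as adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.325), though it was called lower with fry (adjusted p = 0.0236). The desmosomal genes Dsg2 (117 ± 5.64 against 232 ± 14.4 CPM) and Dsp (a log2 fold change of -0.95 ± 0.15 SE) were lower, as was Ctnnd1, which encodes p120 catenin (101 ± 32.4 against 202 ± 15.8). The gap junction gene Gjb1 was higher (65.1 ± 8.53 against 25.6 ± 5.14 CPM; limma, adjusted p = 3.58e-04).

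No other list passed with camera, and most of their members were not called. Of goblet genes 1 of 17 was lower and 0 higher (adjusted p = 0.614), of tuft genes 0 of 12 were called (0.614), and of Notch targets 0 of 7 (0.67). Enteroendocrine genes had 2 of 23 higher (adjusted p = 0.927), among them Ghrl, the gene of ghrelin (507 ± 721 against 21.0 ± 36.6 CPM), and Reg4 (332 ± 96.1 against 114 ± 64.9), which is also the 1 of 9 enterochromaffin genes called (0.927). Ghrl was at 1335, 14.98 and 172.5 CPM in picked replicates 1, 2 and 3 and kept its call in only 15 of 26 settings (limma, adjusted p up to 0.308), and Reg4, with a log2 fold change from 0.15 to 2.74, in 22 of 27. Among enterocyte genes Rbp2 and Prap1 were higher and Apob lower, of 24 (0.927); Prap1 and Apob kept their calls in 22 of 27 settings. Proliferation genes had 3 of 28 higher, Mcm5, Mcm7 and Stmn1, and 1 lower, Hmgb2 (0.614). Mcm5 kept its call in 24 of 27 settings, Mcm7 in 20 and Stmn1, whose log2 fold change fell to 0.04, in 17. Cd74, which takes part in antigen presentation, was the 1 higher of 13 immune genes (1265 ± 150 against 397 ± 135 CPM; list 0.927). Of 20 unfolded protein genes Ddit3 and Atf4 were higher and Canx lower (0.927). Aen was higher and Ccng1 lower among 9 p53 targets (0.927), with calls kept in 20 and in only 10 of 27 settings. The growth factor gene Areg was the 1 higher of 8 niche ligands (0.689), and the nuclear RNA Malat1 was lower among 3 RNA quality genes (0.927). Adjusted over the list alone, the numbers higher and lower were 0 and 1 for goblet, 1 and 0 for enteroendocrine, enterochromaffin, enterocyte, immune and niche ligand, 1 and 1 for proliferation, 2 and 1 for unfolded protein, and 0 and 1 for RNA quality; none of the tuft, p53 and Notch genes passed. Muc2, Chga, Tac1, Dclk1, Mki67 and Apoa1, markers of goblet, enteroendocrine, enterochromaffin, tuft, dividing cells and enterocytes, had adjusted p of 0.338, 0.627, 0.458, 0.141, 0.264 and 0.993 (limma). Several of them were called against a part of the sorted libraries. Against GK5a alone Dclk1 (log2 fold change -4.08, adjusted p = 0.00433) and Apoa1 (-1.49, 0.0161) were lower and Mki67 higher (0.67, 0.00171), and without sorted replicate 6 Dclk1 (adjusted p = 0.0315, limma) and Mki67 (0.0111) were called too. Against GK5b alone Tac1 (-1.76, adjusted p = 0.00684, limma) and Muc2 (-2.38, 0.0364) were lower and Apoa1 higher (3.78, 0.0108). Tac1 was also lower with GK5a summed (-1.50, adjusted p = 0.0169, limma), and Muc2 with the mean of CPM per well (-1.51, 0.0273). Against GK5b libraries alone, which are rich in goblet cells, the goblet and unfolded protein lists were lower in picked libraries (adjusted p = 1.38e-06 and 0.00187) and the enterocyte list higher (7.49e-04); against GK5a libraries alone the tuft list was lower (0.0334).

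In the GRCm38 (mm10) assembly, Rpl38 lies on chromosome 11 from 114668524 to 114672331, Ier3 on chromosome 17 from 35821684 to 35822923, Hspa8 on chromosome 9 from 40800984 to 40810087, Defa24 on chromosome 8 from 21734494 to 21735471, Arpc3 on chromosome 5 from 122391878 to 122414184 and Lgr5 on chromosome 10 from 115450311 to 115587780.

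Wells of picked groups showed fewer genes than wells of single cells. At 2000 transcripts per well, the library median was 1040 ± 12.9 genes (SD, n = 3) in picked and 1200 ± 21.0 (n = 7) in sorted libraries, with all 3 picked libraries below all sorted ones (exact permutation p = 0.0167, the smallest this design can give). The mean was 1209 in GK5a and 1178 in GK5b. Without thinning the medians were 1679 ± 586 and 2962 ± 916. The 100 most abundant genes took 35.5 ± 4.68% of transcripts in picked and 26.0 ± 1.34% in sorted libraries (exact permutation p = 0.0167). Rn45s, the ribosomal RNA precursor, took 3.19 ± 0.754% against 0.482 ± 0.298% (exact permutation p = 0.0167). Without ribosomal protein genes, Rn45s and the Paneth list, the difference in genes per well was -90.3 in place of -160 (exact permutation p = 0.0167).

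The total of transcripts per well did not set picked groups apart. Library medians were 4506 ± 2394 transcripts in picked (n = 3) and 8668 ± 4722 in sorted libraries (n = 7; exact permutation p = 0.167). GK5a libraries averaged 6061 and GK5b libraries 15186. Relative to the spike-in molecules in the same well, the log2 ratio was 5.56 ± 1.05 in picked and 4.91 ± 1.13 in sorted libraries (exact permutation p = 0.467). The difference was 1.31 against GK5a alone (exact permutation p = 0.0714) and turned to -0.98 against GK5b alone (exact permutation p = 0.4). Library medians of the spike-in molecules themselves were 102 ± 72.6 per well in picked and 292 ± 130 in sorted libraries, which also affects this ratio.

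**Figure D2:**
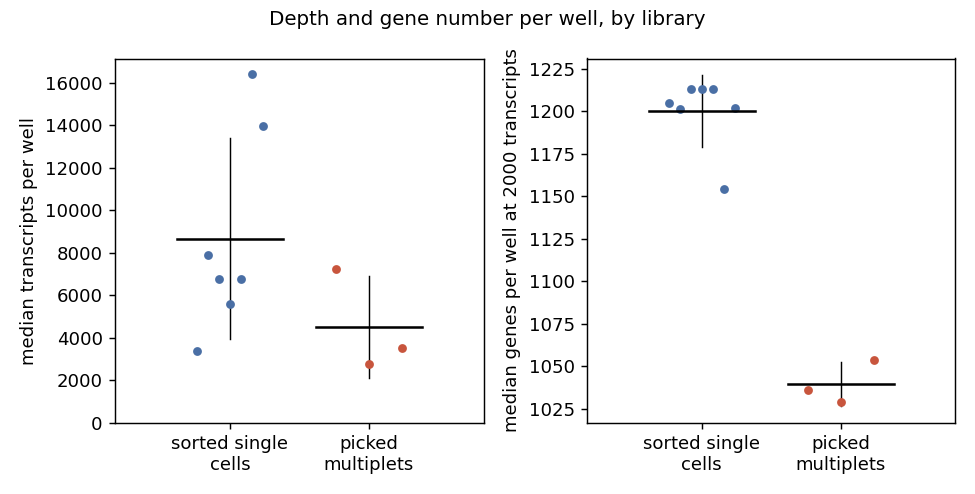
Library medians of transcripts per well (left, axis from 0) and of genes per well at 2000 transcripts (right, axis not from 0), with 1 point per library and the mean with SD in black. The 3 picked libraries lie between 1029 and 1054 genes, below the lowest sorted library at 1154.

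Among sorted cells, progenitor-like wells were the largest class on average. As the class of largest weight, progenitor-like cells led by Lgr5, Gkn3 and Clca4 or by cell-cycle genes such as Mcm5, Ube2c and Ccna2 made up 48.4 ± 13.2% of wells (SD over 7 libraries). Goblet-like cells made up 28.4 ± 22.7%. Their clusters had Muc2, Zg16 and Fcgbp, or Spink4, Rep15 and Fcgbp, among the leading genes, except for a cluster of 117 wells. That cluster was led by Id4, Creb3l1 and Atoh1 with dividing-cell genes such as Mki67 and Top2a. It had 19 progenitor and 8 goblet markers raised, and 60 of its wells were in sorted replicate 6. Enterocyte-like wells with Apoa1, Apoa4 and Reg3b made up 14.2 ± 6.82%. Enteroendocrine-like wells were at 2.93 ± 1.41%, Paneth-like at 2.34 ± 1.55%, tuft-like at 1.76 ± 1.24% and immune-like wells, with Igj and Gzma, at 1.10 ± 0.747%; 0.846 ± 1.53% stayed unnamed. The 5 GK5a libraries were alike, with 16.6 ± 0.688% goblet-like wells, while GK5b replicates 6 and 7 had 76.1% and 39.8%. The labels name no sort gate that would set these shares.

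The share of picked wells in which at least 2 classes were found was 17.3 ± 3.97% (SD, n = 3), against 11.2 ± 3.15% of sorted wells (n = 7). The sorted share serves as the background, though the profiles come from these same sorted wells. The difference did not pass (exact permutation p = 0.0667), and the background was 11.9% in GK5a and 9.55% in GK5b. It passed at the smallest possible p of 0.0167 (exact permutation) with a weight threshold of 0.15 (38.8% against 19.2%), with coarser clusters (21.5% against 11.2%) and with wells thinned to 2000 transcripts (20.2% against 10.8%). With finer clusters the shares were 10.1% against 8.503% (exact permutation p = 0.55), and with a weight threshold of 0.35 they were 7.99% against 5.46% (exact permutation p = 0.2). The first 72 wells of picked replicate 1, which hold blood cell transcripts, are counted in these shares. Of the 122 used wells of that library, 8 were called progenitor-like with immune-like and 1 tuft-like with immune-like. Without the first 72 wells the difference in progenitor-like with immune-like wells went from 1.81 to -0.00595 percentage points. In sums of 2 sorted wells of the same library made by computer, 35.4% showed at least 2 classes on average over the libraries, and both classes were found in 48.2% of the sums whose classes differed. Of the sums of 2 wells of the same class 7.17% showed at least 2, so most pairs of cells of the same class would not be counted as mixed. The sums join the transcripts of 2 whole wells and were fitted to profiles from the same sorted wells. Picked wells differ from them in depth, experiment code and sex. The shares in the sums therefore do not give the share to be found among picked groups.

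None of the 7 classes passed the adjusted threshold in the share of wells that hold it, and 1 had an unadjusted p under 0.05. A difference in 1 class alone could not pass after adjustment, even at the smallest possible p of 0.0167 (exact permutation). Progenitor-like cells were found in 70.7 ± 7.17% of picked and 54.1 ± 14.4% of sorted wells (exact permutation p = 0.0333, adjusted p = 0.233; GK5a 61.0%, GK5b 36.8%). Paneth-like cells were found in 4.49 ± 1.85% against 2.79 ± 1.43% (exact permutation p = 0.267) and goblet-like cells in 17.1 ± 3.02% against 30.2 ± 22.5% (exact permutation p = 0.233). Enterocyte-like cells were in 15.9 ± 6.39% against 17.2 ± 7.87%, enteroendocrine-like in 1.67 ± 0.840% against 3.13 ± 1.49% and tuft-like in 0.646 ± 0.579% against 1.95 ± 1.28%. Immune-like cells were in 6.56 ± 11.4% of picked and 1.41 ± 0.773% of sorted wells; they were nearly all in the first 72 wells of picked replicate 1, which hold blood cell transcripts, and without these wells the difference was -1.04 percentage points.

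**Figure D3:**
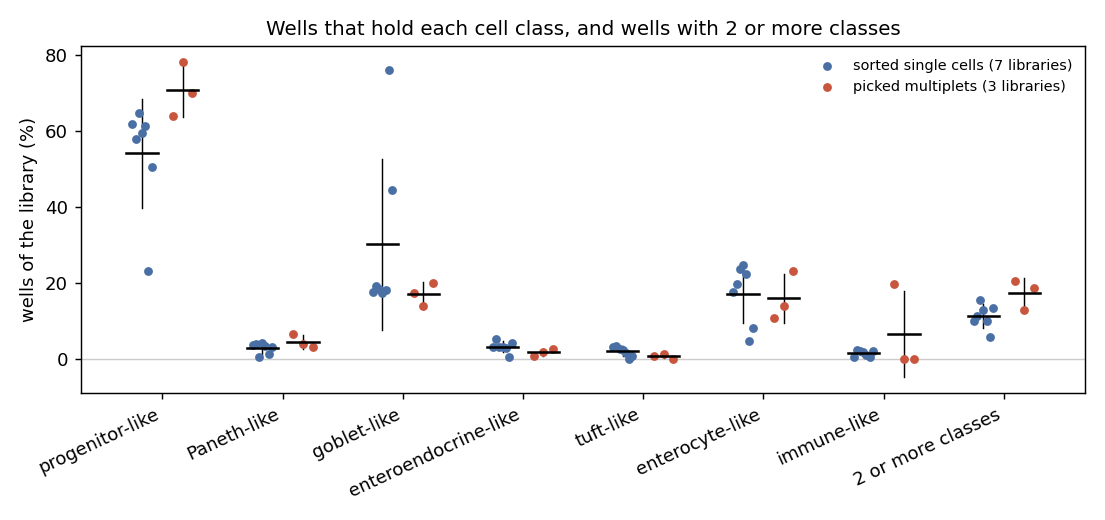
Percentage of used wells that hold each cell class at a weight of at least 0.25, and of wells with at least 2 classes; 1 point per library, with the mean and SD in black. The goblet-like shares of the 2 GK5b libraries, 76.1% and 44.4%, stand above the 5 GK5a libraries.

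The commonest pair of classes in picked wells was progenitor-like with goblet-like, at 6.96 ± 1.78% of wells against 3.86 ± 1.09% in sorted libraries (exact permutation p = 0.0333, adjusted over 21 pairs 0.7; GK5a 3.65%, GK5b 4.39%). Progenitor-like with enterocyte-like followed at 5.08 ± 2.18% against 5.30 ± 2.79% (exact permutation p = 0.9), and progenitor-like with Paneth-like was at 1.15 ± 1.24% against 0.369 ± 0.420% (exact permutation p = 0.25). No pair passed the adjusted threshold and 1 of the 21 had an unadjusted p under 0.05. The goblet-like class includes a cluster with raised progenitor markers, so progenitor-like with goblet-like can also come from a single cell. With 21 pairs, a difference in 1 pair alone could not pass after adjustment at any p this design can give. Partners shuffled within each picked library gave 28.2 wells with progenitor-like and goblet-like cells where 36 were observed, and 27.6 with progenitor-like and enterocyte-like cells where 27 were observed. For progenitor-like with Paneth-like cells 5 were observed and 6.60 were the mean of the shuffles. No pair lay outside the 95% range of the shuffles in at least 2 of the 3 libraries. Paneth-like with goblet-like, with 3 wells observed against 1.17, lay above it in 1 library. The lower end of the range exceeded 0 in at least 2 libraries only for progenitor-like with goblet-like and with enterocyte-like cells. For the other pairs a deficit could therefore not be called. Goblet-like with enterocyte-like cells had 1 well observed against 4.98 in the shuffles.

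**Figure D4:**
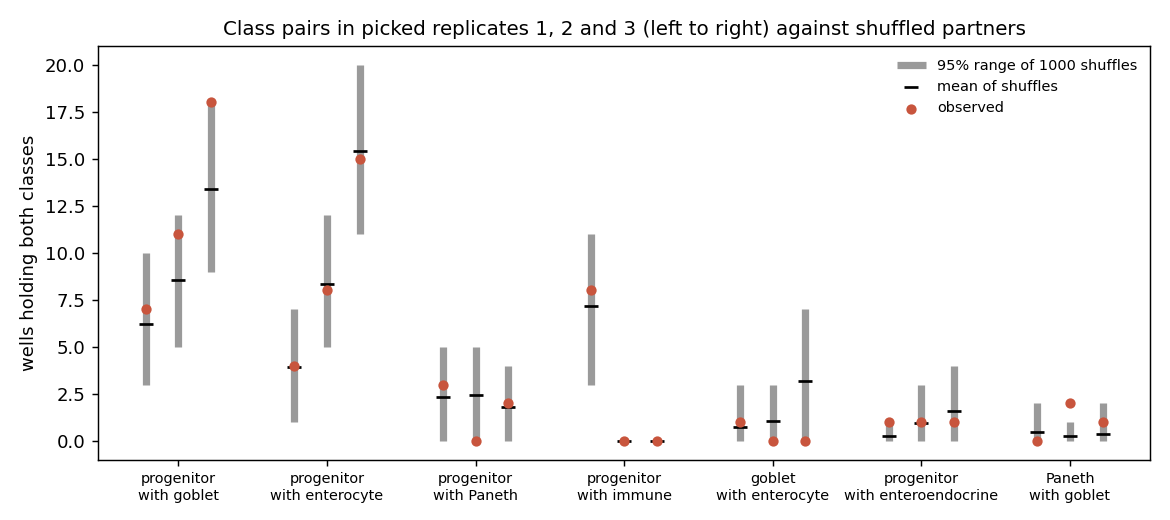
Number of wells holding both classes for 7 of the 21 class pairs, those with at least 3 wells observed or at least 2 in the mean of the shuffles, in picked replicates 1, 2 and 3 from left to right. Grey bars give the 95% range of 1000 shuffles, black ticks their mean and red points the observed number, such as 18 wells with progenitor-like and goblet-like cells in replicate 3.

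Pairs of marker genes in the same well, which need no clusters, gave no call either: 0 of 10 gene pairs passed the exact permutation test and 0 had an unadjusted p under 0.05. After adjustment over 10 pairs, a difference in 1 pair alone could not have passed. For 6 of the 10 pairs at least 1 library had 0 wells with both genes, so their odds ratios there are set by the 0.5 added to each of the 4 counts. Lgr5 and the enterochromaffin gene Tac1, the pair with the lowest p (exact permutation p = 0.0667, adjusted 0.611), shared 1 well over all picked and 2 over all sorted libraries, too few to read. For Lgr5 with Lyz1, which shared wells in every library, the log2 odds ratios were 1.24 ± 1.56 in picked and 0.56 ± 0.60 in sorted libraries (exact permutation p = 0.417). At 2000 transcripts, Lgr5 was seen in 6.10 ± 0.820% of picked and 13.5 ± 5.98% of sorted wells, and Lyz1 in 58.9 ± 33.1% and 26.5 ± 9.46%. Lyz1 reached 92.5% of wells in picked replicate 1, far above its share of Paneth-like wells, so detection of this gene does not mark a Paneth cell.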

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

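Of 104 results over the 7 sorted libraries, 15 had a library far from the other 6 by Dixon's test, where chance gives about 1 in 20. The tests of composition, of sex and batch and of the number of Paneth-like wells were chosen only after the results they address had been seen.

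Sorted replicate 6, a GK5b library, stood apart most often. It had 1154 genes per well at 2000 transcripts, against 1201 to 1213 in the others, and 23.1% of wells with progenitor-like cells, against 50.6% to 64.8%. Its CPM was 11.5 for Lgr5 (others 66.7 to 107.5), 558 for Mki67 (215 to 329), 26.2 for Leprel2 (3.14 to 9.84) and 369 for Atf4 (286 to 316). Its log2 odds ratio of Lgr5 with Chga was 3.48 (-1.86 to 0.22), but 0 wells there held both genes, so this value comes from the 0.5 added to each count. Sorted replicate 1 had a CPM of 14.6 for Ier3 (9.02 to 11.1), 1212 for Hspa8 (1583 to 1726), 8.19 for Areg (0.523 to 3.83) and 53.7 for Mcm5 (78.1 to 92.6). In sorted replicate 2, Defa3 was at 14.8 CPM (0.850 to 6.80) and Dclk1 at 128.6 CPM (0 to 51.1). Hspa1a reached 23.8 CPM in sorted replicate 3 (3.00 to 10.9), and Ghrl 98.0 CPM in sorted replicate 7 (0.205 to 38.4).

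The number of genes called between picked and sorted libraries was 3136. Of 100 splits of the 10 libraries into 7 and 3, 1, the real one, gave as many, and the highest other split gave 61. A random division of the libraries would thus rarely give this number. The real split also divides the libraries by sex and by experiment code, so the splits cannot tell an effect of picking from these. For gene lists a random division often gives as many calls. Of the 100 splits, 67 gave as many as the 5 of the real split. The highest other gave 13, for sorted replicates 2, 3 and 5 against the rest. Why other splits call lists was not tested. The number of list calls is therefore no evidence by itself.

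Ribosomal protein, immediate-early and heat-shock genes were higher in picked libraries. A trend on transcript length or GC content was measured on the longest annotated transcript of each gene. With each library's trend removed, all 3 lists kept an adjusted p under 0.05 (2.9e-15, 4.66e-08 and 1.58e-05 with camera). Their medians went from 1.00 to 0.54, from 1.49 to 1.33 and from 0.70 to 0.83. These values argue against such a trend as the whole cause, but cannot exclude a bias on transcripts other than the longest. List calls also arose in other splits, so a kept call is weak evidence by itself. All 3 lists also kept their calls among wells with a progenitor weight of at least 0.75. This argues against different shares of the fitted classes as the whole cause. It cannot exclude a different mix within the progenitor class, which merges stem and dividing cells. In those wells the stem list was lower (median log2 fold change -0.82, camera, adjusted p = 1.07e-04) and the Paneth list higher (4.38, 4.58e-13). What also stays open is that the libraries differ in animals, sex and experiment code, and perhaps in strain (Pla2g2a, below). Of the 7 sorted libraries, 0 had the sex of the picked ones. The effect of picking and mild dissociation, a biological difference between attached and single cells, and the batch therefore cannot be told apart. A difference in RNA quality or capture stays open too: Rn45s was 6.61-fold higher, Rpph1, which has no poly(A) tail, rose and Malat1 fell (log2 fold change -1.47, limma, adjusted p = 0.0041), while the RNA quality list of 3 tested genes, Malat1 among them, did not pass (camera, adjusted p = 0.927).

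Paneth transcripts were higher in picked libraries. In picked replicate 1, wells almost without epithelial transcripts held 0.785% at the median, where the median well held 0.057 ± 0.051% in sorted libraries. Transfer between wells may account for this, but it was not told apart from a source within those wells. There Lyz1 alone was at 3718 CPM, where the whole list pooled to 0.667%. Whether and how far such transfer carries the rise stays open. In picked libraries, wells under the minimum held 0.142 to 0.617 times the Paneth share of the used wells. A few Paneth-rich wells stay open as the source. The list kept its call without the 5 richest wells of each library (adjusted p = 2.71e-07 with camera). Any RNA spread from these would remain in the other wells, so this cannot exclude them. More wells with a Paneth-like cell also stays open (exact permutation p = 0.2667, 3 against 7 libraries). The call is lost with an estimated correlation, and picking of Paneth cells attached to neighbours stays open too, with too few wells to decide: progenitor-like with Paneth-like cells were in 1.15% of picked and 0.369% of sorted wells (exact permutation p = 0.25), and in 5 picked wells against 6.60 in the shuffles.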

How the results depend on the processing

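Settings chosen after the data were seen are the first 72 wells, progenitor wells, Paneth-richest wells, pseudocounts, precision weights, whole counts, Rn45s, other-library profiles and genes per well without abundant gene groups. No paired analysis was possible because no label pairs a picked with a sorted library. The Wald test named in advance was not run, because the unit stood as other; whole counts could be derived, and limma called 3154 genes on them. Where a result changed, the cause was not tested.

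The number of genes called ranged from 1452 (GK5b alone) and 1457 (GK5a summed into 1) to 4281 (library totals). Of 62 called named genes 45 kept their call in every setting in which they were tested (25 to 27 each), 17 lost it in at least 1 and 0 changed direction. Those 17 kept it as follows: Ccng1 in 10 of 27 settings, Stmn1 in 17, Aen and Mcm7 in 20, Apob, Gkn3, Nrn1, Prap1 and Reg4 in 22, Rgmb in 23, Mcm5 in 24, Cstf2t in 25, Atf4 and Canx in 26, and of 26 settings Ghrl in 15, and Defa5 and Rep15 in 24. Removal of each library's trend on transcript length and GC content is not among these settings. It left 2224 of 9854 genes called in place of 2967, 1779 of them in both, and of 59 named genes with a value 52 kept their call, 7 lost it and 1 turned without a call. Before removal the log2 fold change of all genes had a rank correlation of 0.37 with GC content and -0.25 with length. Lists called went from 5 to 2 with an estimated correlation, and with fry the stem list was lost and the junction and adhesion list called lower (adjusted p = 0.0236). Over 25 settings heat-shock genes kept their call in 25 (median log2 fold change 0.37, with library totals, to 0.97), ribosomal protein genes in 25 (0.66 to 1.03), immediate-early genes in 24 (1.20 to 2.02), Paneth genes in 24 (2.00 to 4.38) and stem genes in 18 (-1.01 to -0.35). Genes per well differed by -138 against GK5b alone (exact permutation p = 0.2) and by -159, -155 and -168 without picked replicates 1, 2 and 3 (exact permutation p = 0.0556); these designs cannot give a lower p. Without a sorted library the range was -168.2 to -158.3. Wells with at least 2 classes differed by 19.6 points at a weight of 0.15, 10.3 with coarser clusters and 9.47 after thinning (exact permutation p = 0.0167 each), but by 1.58 with finer clusters (exact permutation p = 0.55). Coarser clusters put 1 class pair outside the shuffles in 2 libraries, where 0 were before.

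All other changes of direction were in results not called over all libraries. For genes (log2 fold change), Apoa1 turned to 2.004 with GK5a summed, 3.78 against GK5b alone, 0.013 with median-of-ratios factors, 0.041 without the first 72 wells, 0.198 with precision weights, 0.314 in progenitor wells, 0.086 with wells of at least 500 transcripts and 0.033 without the Paneth-richest wells. Olfm4 turned to -0.013 with GK5a summed, -0.068 with library totals, -0.713 in progenitor wells and -0.189 with wells of at least 2000 transcripts. Against GK5b alone Chga went to 0.024, Lgr5 to 0.461 and Mki67 to -0.193, and in progenitor wells Muc2 went to 0.374.

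For lists the direction is that of camera and the values are median log2 fold changes. Against GK5a alone, enteroendocrine (-0.289), goblet (0.323), p53 (-0.089) and unfolded protein (0.018) genes turned. Against GK5b alone, enterocyte (0.944), immune (-0.243) and tuft (0.815) genes turned. Enterochromaffin (-0.838), enterocyte (-0.348) and immune (-0.902) genes turned with library totals. Enteroendocrine genes also turned with fry (-0.273), a pseudocount of 5 (-0.256), at least 2000 (-0.353) and at least 500 transcripts (-0.276), and immune genes with at least 2000 (-0.752). Enterocyte genes turned without the first 72 wells (0.027) and without the Paneth-richest wells (-0.035). In progenitor wells, enterochromaffin (1.645), enterocyte (0.166), goblet (0.503), immune (0.535), proliferation (-0.175) and unfolded protein (0.007) genes turned.

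For classes and pairs, in percentage points, GK5b alone gave 9.58 for enterocyte-like, 0.263 for tuft-like, -0.223 for Paneth-like with goblet-like and 2.79 for progenitor-like with enterocyte-like wells. Finer clusters gave 0.0791 for goblet-like with enterocyte-like and -1.26 for progenitor-like with goblet-like wells. A weight of 0.15 gave 1.58 for goblet-like with enterocyte-like, 1.90 for progenitor-like with enterocyte-like and 0.854 for enterocyte-like wells, and 0.35 gave 0.0726 for goblet-like with enterocyte-like and -0.138 for progenitor-like with Paneth-like. Without the first 72 wells progenitor-like with enterocyte-like was at 0.155, progenitor-like with immune-like at -0.00595 and immune-like at -1.04. After thinning, progenitor-like with enterocyte-like was at 0.146. The log2 ratio to spike-ins turned to -0.98 (-0.979) against GK5b alone.

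For marker pairs (difference of log2 odds ratios), GK5a alone gave -0.163 for Lyz1 with Chga and -0.266 for Lyz1 with Mki67, and GK5b alone -1.77 for Lgr5 with Apoa1 and -0.914 for Lgr5 with Dclk1. Both GK5b libraries had 0 wells with Lgr5 and Apoa1 and 0 with Dclk1, so the last 2 values rest on the 0.5 added to each count. Lyz1 with Chga too had 0 shared wells in 2 libraries. Detection at 3 transcripts gave -0.251 for Lgr5 with Lyz1, -1.12 for Lyz1 with Chga, -0.399 for Lyz1 with Mki67 and -2.23 for Lyz1 with Muc2. Thinning to 1000 gave -0.367 for Lgr5 with Apoa1, -0.659 for Lyz1 with Chga and -0.652 for Lyz1 with Muc2, and no thinning -0.265 for Lyz1 with Mki67.

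Leaving out 1 library at a time changed the direction of Paneth-like with goblet-like (-0.0345 to 0.524), progenitor-like with enterocyte-like (-1.43 to 0.685), progenitor-like with immune-like (-0.372 to 2.91), enterocyte-like (-4.86 to 1.31) and immune-like wells (-1.41 to 8.43). For lists it did so for enterochromaffin (-0.669 to -0.13), enterocyte (-0.744 to 0.27), enteroendocrine (-0.444 to -0.092), immune (-1.838 to 0.252), p53 (-0.319 to 0.177), RNA quality (-0.141 to 0.055) and unfolded protein genes (-0.35 to -0.103). It also did so for Apoa1 (-0.806 to 0.349), Chga (-1.248 to 0.163), Lgr5 with Apoa1 (-0.414 to 0.780), Lgr5 with Lyz1 (-0.223 to 1.19), Lyz1 with Chga (-0.882 to 0.952) and Lyz1 with Mki67 (-0.294 to 0.355).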

Other observations

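The first 72 wells of picked replicate 1, which are 3 plate rows if wells are numbered along rows of 24, held transcripts of marrow and blood cells. The tests of this pattern were chosen after it had been seen, from lists of 17 marrow and 10 epithelial genes. In the 31 used wells there, marrow genes took 9.23% of transcripts at the median, led by S100a9 (34836 CPM), S100a8 (26729 CPM), Ngp (13330 CPM), Camp (12145 CPM), Elane (4391 CPM) and Mpo (3578 CPM), against 0.132% in the other 91 wells and 0% at the median of each other library. The median epithelial share there was 0.0202 times that of the other wells of the plate, and Epcam was at 0 CPM against 511 CPM. Blood cells attached to crypt cells are thereby excluded, and the wells may hold cells of another tissue, such as marrow. The same wells had Paneth list transcripts at 0.785% of the median well and Lyz1 at 3718 CPM. Leaving them out gave 3193 called genes in place of 3136.

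Pla2g2a, a secreted phospholipase of Paneth and goblet cells, differed between libraries of the same group; it was chosen after its values had been seen. It was at 15771 CPM in picked replicate 1 but at 129 and 38.7 CPM in picked replicates 2 and 3, and from 1189 to 6671 CPM in sorted libraries. Per 1000 transcripts of the Paneth and goblet lists this came to 2.16 and 1.47 in picked replicates 2 and 3, against 67.9 to 126.6 in the other 8 libraries. The highest of the 2 was 0.0318 times the lowest of the other 8, so fewer Paneth and goblet transcripts do not account for it. The gene carries a disabling frameshift in C57BL/6 mice, the strain that the labels give for every library, so whether that strain is right for all of them stays open. By this gene, picked replicates 2 and 3 stand apart from picked replicate 1 and from all 7 sorted libraries. A difference in strain would thus be partly confounded with the group. This 1 gene cannot show that picked replicate 1 shares the strain of the sorted libraries. Fabp6, the bile acid binding protein of the ileum, was at 1262 ± 817 CPM in picked (SD, n = 3) and 319 ± 207 CPM in sorted libraries (n = 7), with 2.28 CPM in sorted replicate 6.

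In sorted replicate 7, kidney genes took 7.59% of the transcripts of well 28 and 8.48% of well 200, and stomach genes 4.29% of well 235. In all other used wells these lists reached at most 0.376% and 0.094%. Wells under the minimum held a larger share of Paneth transcripts than used wells in 6 of the 7 sorted libraries, with a mean ratio of 4.25 ± 3.78 (SD, n = 7).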
